A study of Homo sapiens with 9 samples.

How the data were processed

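Tumour RNA of 9 xenografts was hybridized to Affymetrix human HG-U133 Plus 2.0 arrays, 1 array a sample, with 3 arrays in each of 3 groups (control, DBZ, bevacizumab). The protocol names 5 mice a group, and the labels do not say whether each array holds the tumour of a different mouse, so the p-values measure the spread between these samples. The dose of bevacizumab was 10 mg/kg; that of DBZ is 8.1 in the labels' unit of mmol/kg, a unit that was not checked. The deposited values are log2 signals made with GCRMA after scanning with GCOS 1.1.1.052, per the submitters' processing notes; the log base is not written in the file and was taken from the method and from the range of the values, whose medians lie at 2.99 to 3.06 in the 9 arrays. The probe definition behind these values is not stated. The table held 54675 probe sets with no missing values.

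Probe sets were named through the platform's annotation, with symbols updated by Entrez number from a table of RefSeq genes (41043 probe sets matched). Of the probe sets 41097 had 1 gene symbol, 1801 had several and 11777 had none; the latter kinds, and 62 control probe sets, stayed out of the tests. CA9 had no probe set with only its own symbol and is not analysed here. A probe set was kept when it lay above its array's median in at least 3 of 9 arrays, and each gene was represented by its kept probe set with the highest mean over the 9 arrays, which left 11957 genes from 22437 probe sets. No further normalization was applied. The number of arrays limits the precision, and signals near the array median carry little information on order.

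Group means were fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), so that the 3 groups shared 1 estimate of the spread with 6 residual degrees of freedom, and 3 contrasts were tested with Benjamini-Hochberg adjustment over the genes at a threshold of 0.05. A gene "rose" or "fell" when it passed. The 39 gene lists of pathways, complexes and other cell types were fixed from textbook knowledge before the data were examined, as were the tests and the choice of named genes; 37 lists had at least 5 tested members (host adipocytes had 1 and red blood cells 3). They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists. The estimate lay below this preset for several lists. It was -0.036 for Notch targets, -0.018 for p53 targets and for YAP and TEAD targets, and -0.008 for TGF-beta targets. For macrophage and granulocyte markers it was -0.02, and for autophagy and lysosome 0.008. Where these lists had passed, a higher correlation was therefore not the source of their larger p. Camera compares a list with all other genes; fry does not. All medians and changes are differences of log2 values.

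The genes named in the text are the 8 largest rises and 8 largest falls among genes that passed and whose 3 arrays in each group did not overlap, up to 4 members with the smallest p, in the list's direction, of each list that passed camera, and 18 genes of Notch signalling, hypoxia and lipid metabolism fixed in advance, given in the comparisons with control. Genes named outside this rule are marked. At least 1 further kept probe set went in the other direction for MVK, PLK3, INHBA, JAG1 and FABP7 with bevacizumab, for HELLS, DERL1, ADAM12 and JAG1 with DBZ, and for DKK2, HERPUD1, XBP1, BECN1, PHLDA3, AURKB and RBMS3 between the treatments. The groups did not overlap in 18.1%, 17.2% and 18.5% of genes in the 3 contrasts (bevacizumab against control, DBZ against control, bevacizumab against DBZ), against 10% by chance.

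On simulated data with 11957 genes, the fit recovered 94%, 92% and 95% of genes changed by 1 log2 unit and 66%, 65% and 62% of those changed by 0.5 in these contrasts, with 7.51%, 5.42% and 6.55% false calls. In the simulation of bevacizumab against control, camera found 20 of 20 lists of 20 genes raised by 0.3 and called 1 of 740 unchanged lists. Smaller shifts of lists were not simulated. Genes were drawn independently there, while the correlation estimated in the real data reached 0.712 in the ATF4 list. The count of unchanged lists called is therefore no false call rate for these data. The correlation, covariance and shared signs of the 2 treatments' effects were set against 100 simulations in which all groups were unchanged and both comparisons shared their controls. In these simulations all groups had the same spread.

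The alternatives were no filter or a stricter one (65th percentile), quantile normalization, centring of each array on its median, an offset of 16 before the logarithm, the mean of all probe sets of a gene, only probe sets without the suffixes that mark shared sequence, eBayes with trend and robust settings, array weights, a fold change of at least 1.5, only the 6 arrays compared, the replicate number as a block, and each array left out in turn. Added after seeing the data were the omission of control 3 with bevacizumab 3 (the arrays farthest from the others of their group, at a root mean square distance of 0.288 and 0.228 against 0.144 to 0.223 for the other 7), the omission of DBZ 2 with bevacizumab 3, and the mean of the bacterial spike-ins as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.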

Results

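Gene expression was measured on human whole-genome expression arrays in subcutaneous xenografts of U87-EV, a line derived from the established human glioblastoma line U87, grown in immunodeficient SCID mice. There were 9 arrays in 3 groups of 3. Mice of the control group had received saline. The second group had received dibenzazepine (DBZ), which blocks gamma-secretase, the protease that activates Notch receptors. The third had received bevacizumab, an antibody against the vessel growth factor VEGF. Treatment began at a tumour volume of 0.35 to 0.45 cm3, 2 doses were given 3 days apart, and tumours were taken 4 hours after the second. The tumours held mouse stroma, and mouse RNA can bind to human probes where the sequences are alike. A level on the array is therefore not assigned here to tumour or host cells. The values are log2 GCRMA signals, with a median over all probe sets of 2.99 to 3.06 in each array, and 11957 genes were tested. The number of arrays limited the precision.

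The comparison of bevacizumab with control asked what a short blockade of VEGF changed in the tumour. HEY1, a transcriptional repressor induced by Notch signalling, fell from 9.17 ± 0.07 to 7.51 ± 0.15 (log2 signal, mean ± SD, n = 3). Its relative HEYL fell from 5.50 ± 0.54 to 2.92 ± 0.01, close to the array median. The matrix proteoglycan genes BGN (log2 change -1.87), DCN (-1.40) and LUM (-0.82, against -1.71 in its other probe set) fell, each with the 3 treated arrays below the 3 controls. FRZB, a secreted Wnt antagonist, fell by 2.09 ± 0.11 (SE), and CD248, a surface protein of pericytes and stromal fibroblasts, fell by 1.75 ± 0.08. Across all genes tested, limma called 192 changed (adjusted p under 0.05), 34 higher and 158 lower. Of these, 8 higher and 119 lower genes differed at least 1.5-fold.

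Of the 18 genes of the Notch target list, 10 were tested. Of these, 4 fell (HEY1, HEYL, HEY2 and the receptor gene NOTCH3), none rose and 6 did not pass. When adjusted over the list alone, 6 fell. The median log2 change of the list was -0.57 (camera adjusted p = 1.17e-06). Without the filter on low values it was -0.08. The Notch target list had adjusted p = 0.0523 with an estimated correlation. HES1, another direct Notch target, had a log2 change of -0.82 ± 0.17 (SE, adjusted p = 0.0657). In the collagen list 5 of 28 members fell and 23 did not pass, with 15 fallen when adjusted over the list alone. Its median was -0.39 (adjusted p = 6.32e-10). The collagen list had adjusted p = 0.18 with an estimated correlation. The fibrillar collagen chains among the 5 were COL11A1 (-2.18 ± 0.20), COL5A3 (-1.27 ± 0.18), COL5A1 (-0.61 ± 0.09) and COL3A1 (-0.59 ± 0.09, named after its value was seen). COL11A1 had 3 kept probe sets, from -2.18 to -0.11, and a change of -1.23 by the mean of its probe sets. The fifth was POSTN, which encodes the matrix protein periostin (-0.62 ± 0.07).

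Among 16 markers of fibroblasts and pericytes, 7 fell with bevacizumab, none rose and 9 did not pass, with 10 fallen when adjusted over the list alone. The median was -0.53 (adjusted p = 4.06e-09). The pericyte list had adjusted p = 0.0614 with an estimated correlation. It included RGS5, a G-protein regulator of pericytes (-1.40 ± 0.13), and the smooth muscle actin gene ACTA2 (-0.68 ± 0.08). RGS5 had 6 kept probe sets, from -1.54 to -0.02, and a change of -0.85 by their mean. Some of these markers stand in other lists too, such as NOTCH3 in the Notch target list and COL3A1 in the collagen list. The 10, 28 and 16 tested members of the Notch target, collagen and marker lists were 50 different genes together. These lists are therefore not independent. In the TGF-beta target list 1 of 20 members fell, TAGLN, an actin-binding protein of smooth muscle (-1.35 ± 0.12), and 19 did not pass. Adjusted over the list alone, 1 fell, and the median was -0.22 (adjusted p = 0.0171). The TGF-beta list had adjusted p = 0.179 with an estimated correlation. SMAD7 (-0.57 ± 0.16, adjusted p = 0.148), INHBA (-0.61 ± 0.26, adjusted p = 0.3) and ID3 (-0.54 ± 0.23, adjusted p = 0.306) did not pass.

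**Figure D1:**
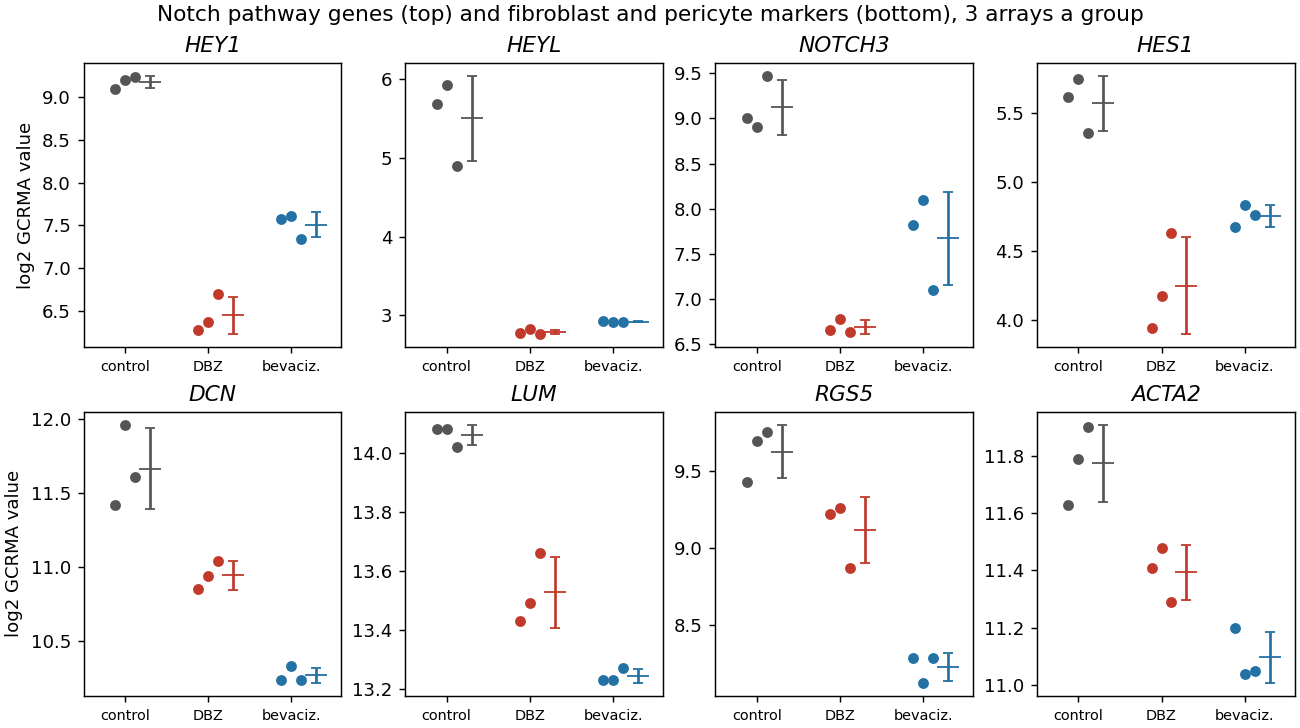
Log2 GCRMA signal of 4 Notch pathway genes (upper row) and 4 fibroblast and pericyte markers (lower row), with a point for each array and the mean and SD of 3 arrays beside it, on a separate vertical range for each gene. HEY1 had means of 9.17 in controls, 7.51 with bevacizumab and 6.45 with DBZ, and DCN 11.66, 10.27 and 10.94, while the lower values of HES1 with bevacizumab and of RGS5 and ACTA2 with DBZ did not pass the test.

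The lists of lipid synthesis had medians above 0 with bevacizumab. INSIG1, an endoplasmic reticulum protein that restrains sterol synthesis, rose by 0.78 ± 0.10 (SE, log2), and STARD4, a sterol carrier, by 0.50 ± 0.08. The other 12 of the 14 tested genes of the cholesterol synthesis list did not pass, among them HMGCS1 (0.56 ± 0.18, adjusted p = 0.187) and MVK (0.27 ± 0.10, adjusted p = 0.252). EBP, an enzyme of cholesterol synthesis outside the list, rose by 0.24 (adjusted p = 0.0389, named after its value was seen). Adjusted over the list alone, 3 rose and 1 fell, and the median was 0.28 (adjusted p = 0.000766). The cholesterol list had adjusted p = 0.701 with an estimated correlation. None of the 11 fatty acid synthesis genes passed, 2 rose when adjusted over the list alone, and the median was 0.14 (adjusted p = 0.00688). The fatty acid list had adjusted p = 0.445 with an estimated correlation. The desaturase gene SCD differed by 1.24 ± 0.26 (adjusted p = 0.0666) and FASN, fatty acid synthase, by 0.59 ± 0.19 (adjusted p = 0.195). SREBF1, which encodes a lipid-regulating transcription factor, differed by 0.28 ± 0.07 (adjusted p = 0.109) and THRSP by 0.14 ± 0.09 (adjusted p = 0.491).

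The ATF4 and amino acid response list, with 34 genes of which none passed and 1 rose when adjusted over the list alone, had a median of 0.25 with bevacizumab (adjusted p = 0.000766). The ATF4 list had adjusted p = 0.842 with an estimated correlation. Its members included CHAC1, a glutathione-degrading enzyme (0.75 ± 0.15, adjusted p = 0.0519), VLDLR (0.52 ± 0.14, adjusted p = 0.13), NARS1 (0.22 ± 0.07, adjusted p = 0.186) and SESN2 (0.60 ± 0.23, adjusted p = 0.267). None of 23 p53 target genes passed, 2 rose when adjusted over the list alone, and the median was 0.08 (adjusted p = 0.00403). The p53 list had adjusted p = 0.115 with an estimated correlation. It held the death receptor gene TNFRSF10B (0.19 ± 0.04, adjusted p = 0.0679), DDB2 (0.32 ± 0.07, adjusted p = 0.0804), PLK3 (0.36 ± 0.11, adjusted p = 0.183) and the cyclin kinase inhibitor gene CDKN1A (0.31 ± 0.10, adjusted p = 0.195).

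The other large rises with bevacizumab were DPP4, a cell surface peptidase (0.89 ± 0.16 SE), the adhesion receptor gene ADGRF4 (0.80 ± 0.15, against 0.26 in its other probe set), the tetraspanin gene CD9 (0.74 ± 0.11) and TMEM71 (0.70 ± 0.13). GSAP, an activator of gamma-secretase, rose by 0.61 ± 0.07 and the long non-coding RNA OLMALINC by 0.56 ± 0.08, from 3.17, near the array median, so the size of this rise is uncertain. CTSLP8, a cathepsin L pseudogene, rose by 0.75 ± 0.12, but its signal is uncertain because it resembles the parent gene. The other large falls were WFDC1 (-2.89 ± 0.43), CILP, a matrix protein of cartilage (-2.44 ± 0.42), and NDST4, a heparan sulfate modifying enzyme (-2.08 ± 0.15). NDST4 lay at 5.33 to 5.36 in the bevacizumab arrays, and COL11A1 at 5.75 to 5.78. Values this flat may mark a floor, so the size of these 2 falls is uncertain.

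VEGFA, which encodes the antigen of bevacizumab, differed by 0.37 ± 0.17 (adjusted p = 0.364) and did not pass. Neither did the hypoxia-responsive genes ADM (0.17, adjusted p = 0.577) and NDRG1 (0.15, adjusted p = 0.838) or the glucose transporter gene SLC2A1 (0.02, adjusted p = 0.977). The Notch receptors NOTCH1 (-0.30, adjusted p = 0.0927) and NOTCH2 (-0.12, adjusted p = 0.703) and the ligands JAG1 (-0.45, adjusted p = 0.299) and DLL4 (0.16, adjusted p = 0.541) did not pass. DLL4 lay at 5.24 to 5.29 in all arrays but control 2, at 4.81, so little can be read from its result. Glycogen phosphorylase PYGL (-0.13, adjusted p = 0.647), the fatty acid binding protein FABP7 (0.04, adjusted p = 0.951) and the lipid droplet protein PLIN2 (0.02, adjusted p = 0.874) did not pass either. PLIN2 had 1 kept probe set, at 3.1 to 3.22 in all 9 arrays. That is near the array median, so little can be read from its result.

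The bevacizumab calls rested on all 9 arrays in 1 limma fit with 6 residual degrees of freedom. Leaving out bevacizumab 1, 2 or 3 left 83, 62 or 59 changed genes. Leaving out DBZ 1, 2 or 3, which enter through the shared spread, left 115, 100 or 116. Of the 192 genes, 40 (3 higher, 37 lower) passed with each array left out. They included HEY1, HEYL, BGN, DCN, LUM, FRZB, CD248, COL11A1, NDST4, POSTN, RGS5, TAGLN, INSIG1 and GSAP. With only the 6 arrays compared, 0 genes were called higher and 28 lower, and INSIG1 and GSAP lost their calls with unchanged differences of 0.78 and 0.61. The other named calls were lost with at least 1 array left out, and the highest adjusted p of all of them but COL3A1 and EBP is given here. Without bevacizumab 3 it was 0.132 for ADGRF4, 0.0972 for CTSLP8, 0.12 for TMEM71, 0.0904 for OLMALINC and 0.0852 for WFDC1. The same array gave 0.11 for HEY2, 0.08 for COL5A1 and 0.0555 for ACTA2. Without bevacizumab 1 it was 0.0506 for CD9 and 0.0597 for COL5A3, and without bevacizumab 2 it was 0.0641 for STARD4. Without control 3 it was 0.0882 for DPP4 and 0.0812 for NOTCH3, and without control 2 it was 0.0882 for CILP. Most of these calls did not hang on that array alone. Over the 9 omissions DPP4 and NOTCH3 kept their calls in 1, and CILP, HEY2, ADGRF4 and TMEM71 in 2. The rest of the calls given here were kept in 3 to 8. The fatty acid synthesis list lost its call without bevacizumab 2 (adjusted p = 0.151). The ATF4 list lost it without control 3 (adjusted p = 0.344) or bevacizumab 2 (0.281), and the TGF-beta list without control 3 (0.0533).

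Bacterial transcripts spiked into the hybridization were lower in all 3 bevacizumab arrays (mean log2 signal 11.27) and all 3 DBZ arrays (11.3) than in all 3 controls (11.5). The exact two-sided permutation p was 0.1 for each treatment, the smallest that 3 against 3 arrays can give. Poly-A transcripts, the other bacterial spike-ins, were lower by more (7.85 with bevacizumab and 8.06 with DBZ, against 8.33 in controls). The 3' minus 5' difference of the GAPDH control probe sets was -0.03 with each treatment and 0.03 in controls. In both of these measures too the 3 arrays of each treatment lay below the 3 controls, at the same p of 0.1. With the mean of all spike-ins as a covariate, a setting chosen after seeing the data, limma called 3 genes changed with bevacizumab and 7 with DBZ. Of these, 1 and 4 were among the genes called without the covariate. The changes of the genes that had fallen stayed closer to their size than the calls did. The median change of the genes that had fallen went from -0.84 to -0.69 with bevacizumab and from -0.77 to -0.72 with DBZ, and 0 of the genes called before changed sign. Some rises with bevacizumab shrank more in at least 1 of all the settings tried. The lowest change there was 0.11 for DPP4 (0.89 in the main fit), 0.29 for CD9 (0.74) and 0.43 for INSIG1 (0.78). For GSAP it was 0.56 (0.61). With the covariate standard errors grew, for HEY1 from 0.12 to 0.27 with bevacizumab and to 0.20 with DBZ.

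The comparison of DBZ with control asked what inhibition of gamma-secretase changed. HEY1 fell from 9.17 ± 0.07 to 6.45 ± 0.22 (log2 signal, mean ± SD, n = 3), and HEYL fell from 5.50 ± 0.54 to 2.79 ± 0.03, below the array median. NOTCH3, a receptor of pericytes and vascular smooth muscle, fell from 9.12 ± 0.30 to 6.69 ± 0.08, and HES1 from 5.57 ± 0.20 to 4.25 ± 0.35. The collagen gene COL5A3 (log2 change -2.71 ± 0.18 SE) and the collagenase gene MMP13 (-2.53 ± 0.38) fell too. The gelatinase gene MMP9 (-2.90 ± 0.42) fell to 3.44, near the low values of the array. Across all genes, limma called 149 changed, 39 higher and 110 lower, of which 4 and 80 differed at least 1.5-fold.

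Among the 10 Notch target genes 5 fell with DBZ, none rose and 5 did not pass. The 5 were HEY1, HEYL, NOTCH3, HES1 and HEY2, the last named after its value was seen. When adjusted over the list alone, 7 fell and 1 rose, and the median was -0.56 (adjusted p = 7.13e-08). Without the filter on low values it was -0.09. The Notch target list had adjusted p = 0.0347 with an estimated correlation, the only list of this comparison to pass in that way. In the collagen list 5 of 28 members fell and 23 did not pass, with 9 fallen when adjusted over the list alone and a median of -0.24 (adjusted p = 2.67e-12). The collagen list had adjusted p = 0.196 with an estimated correlation. Besides COL5A3 the 5 were COL5A1 (-0.62 ± 0.09), COL5A2 (-0.64 ± 0.10), POSTN (-0.65 ± 0.07) and SERPINH1, a collagen chaperone (-0.59 ± 0.10, named after its value was seen).

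Of the 16 fibroblast and pericyte markers 3 fell with DBZ, NOTCH3, LUM (-0.53 ± 0.06, against -1.28 in its other probe set) and DCN (-0.72 ± 0.12), and none rose. The 13 that did not pass included PDGFRB (-0.68 ± 0.14, adjusted p = 0.0793), and 11 fell when adjusted over the list alone. The median was -0.45 (adjusted p = 1.72e-09). The pericyte list had adjusted p = 0.0582 with an estimated correlation. The list of matrix proteases and their inhibitors is called the matrix protease list here. In it 3 of 24 genes fell, MMP9, MMP13 and the stromelysin gene MMP11 (-1.25 ± 0.15). ADAMTS1 rose (0.47 ± 0.07, named after its value was seen) and 20 genes did not pass, ADAM12 among them (-0.40 ± 0.10, adjusted p = 0.117). Adjusted over the list alone, 5 fell and 2 rose, and the median was -0.21 (adjusted p = 0.00229). The matrix protease list had adjusted p = 0.214 with an estimated correlation.

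The cell cycle lists had medians slightly above 0 with DBZ. None of the 34 genes of G2 and mitosis passed over all genes tested, while 11 rose when adjusted over the list alone. The median was 0.17 (adjusted p = 9.94e-11). The G2 list had adjusted p = 0.214 with an estimated correlation. KIF23, a kinesin of cell division, differed by 0.38 ± 0.07 (adjusted p = 0.0684), against 0.03 in its other probe set. The spindle checkpoint kinase gene BUB1 differed by 0.29 ± 0.06 (adjusted p = 0.0804). KIF11 differed by 0.27 ± 0.07 (adjusted p = 0.152) and BUB1B by 0.21 ± 0.06 (adjusted p = 0.165). None of 34 S phase genes passed, 3 rose and 1 fell when adjusted over the list alone, and the median was 0.11 (adjusted p = 9e-06). The S phase list had adjusted p = 0.214 with an estimated correlation. Its leading members were UHRF1, which maintains DNA methylation (0.25 ± 0.05, adjusted p = 0.0783), and the replication clamp gene PCNA (0.21 ± 0.05, adjusted p = 0.118). The helicase subunit genes MCM7 (0.15 ± 0.04, adjusted p = 0.154) and MCM3 (0.17 ± 0.05, adjusted p = 0.178) followed.

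Glycolysis genes had a median of 0.16 with DBZ (adjusted p = 8.58e-06). None of 20 passed, and 1 rose and 1 fell when adjusted over the list alone. The glycolysis list had adjusted p = 0.245 with an estimated correlation. ENO1 differed by 0.23 ± 0.04 (adjusted p = 0.0541), ENO2 by 0.71 ± 0.21 (adjusted p = 0.21), LDHA by 0.15 ± 0.05 (adjusted p = 0.21) and PGAM1 by 0.13 ± 0.05 (adjusted p = 0.289). Other targets of the hypoxia factor HIF had a median of 0.19 (adjusted p = 0.0102), with none of 33 passed and 1 risen when adjusted over the list alone. The HIF list had adjusted p = 0.657 with an estimated correlation. The vasodilator gene ADM differed by 0.64 ± 0.13 (adjusted p = 0.0721), VEGFA by 0.57 ± 0.17 (adjusted p = 0.219) and ZNF395 by 0.83 ± 0.29 (adjusted p = 0.275). EGLN1, an oxygen-sensing hydroxylase, differed by 0.33 ± 0.13 (adjusted p = 0.352), with 0.02 in the lowest of its 3 probe sets.

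None of the 14 tested genes of the cholesterol synthesis list passed with DBZ and 1 rose when adjusted over the list alone (median 0.21, adjusted p = 0.00196). EBP, outside the list, rose by 0.36 (adjusted p = 0.0112, named after its value was seen). The cholesterol list had adjusted p = 0.516 with an estimated correlation. Its named members STARD4 (0.32), INSIG1 (0.30), MVK (0.26) and HMGCS1 (0.33) did not pass. The immediate early list, which also responds to tissue handling, had a median of 0.17 (adjusted p = 0.0106), with none of 19 passed and 1 risen when adjusted over the list alone. The immediate early list had adjusted p = 0.352 with an estimated correlation. It included the transcription factor genes KLF4 (0.52 ± 0.11, adjusted p = 0.0852), KLF6 (0.26 ± 0.07, adjusted p = 0.165) and JUN (0.19 ± 0.07, adjusted p = 0.29). The phosphatase gene DUSP1 differed by 0.38 ± 0.13 (adjusted p = 0.258), against 0.06 in its other probe set.

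Endoplasmic reticulum chaperones had a median of -0.12 with DBZ (adjusted p = 0.000349), with none of 22 passed over all genes or over the list alone. The chaperone list had adjusted p = 0.214 with an estimated correlation. DNAJB11 (-0.19), DNAJB9 (-0.27), DERL1 (-0.14) and MANF (-0.17) were its members with the smallest p. Subunits of oxidative phosphorylation had a median of -0.05 (adjusted p = 0.00228), with none of 41 passed and 1 fallen when adjusted over the list alone. The oxidative phosphorylation list had adjusted p = 0.55 with an estimated correlation. NDUFS3 (-0.22), NDUFB2 (-0.18), SDHD (-0.16) and COX7B (-0.17) led it.

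**Figure D2:**
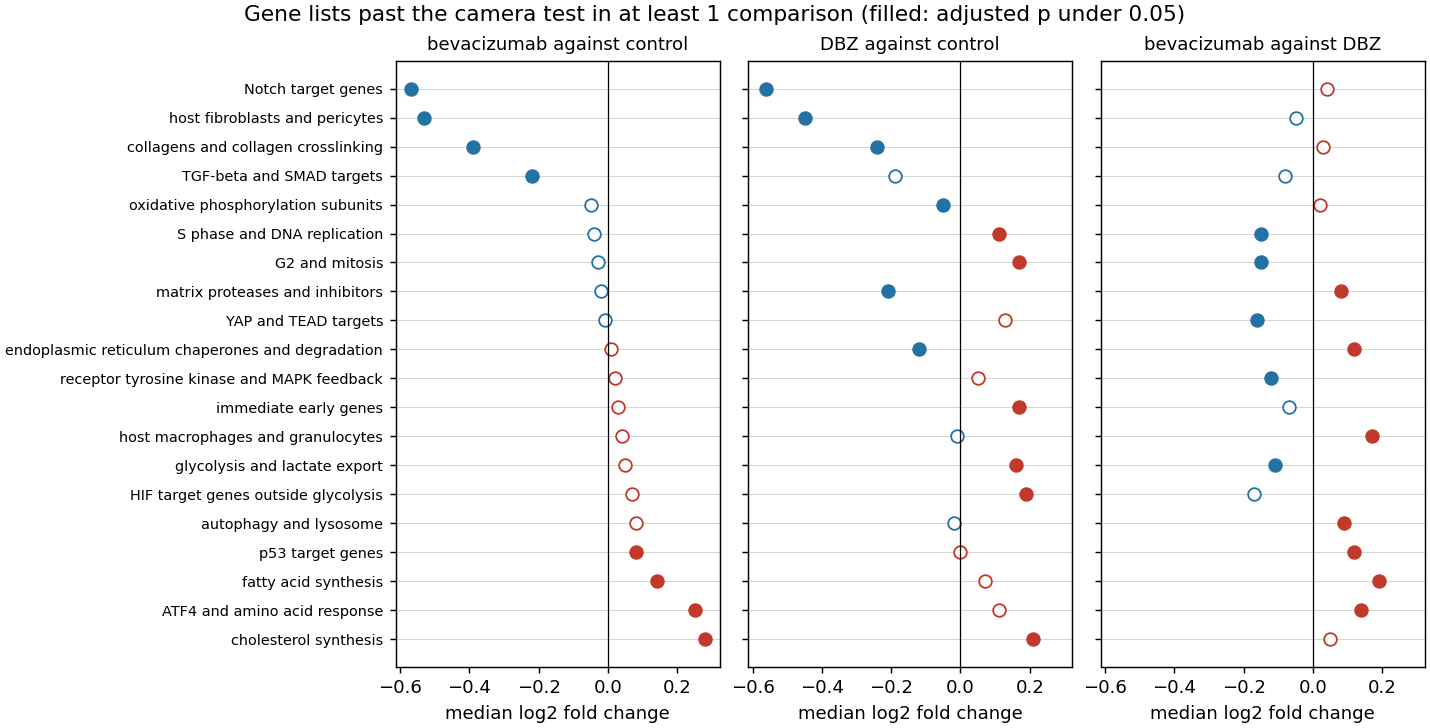
Median log2 fold change of the members of each gene list that passed the camera test (adjusted p under 0.05, preset correlation) in at least 1 comparison, with filled points where it passed, red above and blue below 0. The Notch target list had medians of -0.57 with bevacizumab and -0.56 with DBZ, and the G2 and mitosis list of -0.03 and 0.17.

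The largest rises with DBZ were AOX1, an aldehyde oxidase (0.95 ± 0.12 SE), the scaffold gene AHNAK2 (0.66 ± 0.07), STX1A, a syntaxin of vesicle fusion (0.63 ± 0.11), and the carboxypeptidase gene CPA4 (0.62 ± 0.08). SERTAD2 (0.58 ± 0.10), NRIP3 (0.57 ± 0.06), the chromatin remodeller gene HELLS (0.56 ± 0.10, with -0.02 in the lowest of its 5 probe sets) and the chromatin protein gene HMGA1 (0.55 ± 0.10) also rose. Other large falls were CCDC102B (-2.17 ± 0.12) and IBSP, bone sialoprotein (-2.62 ± 0.44, against -0.11 in its other probe set). IBSP fell to 3.51, near the low values of the array, so the size of its fall is uncertain. NDRG1 (0.55, adjusted p = 0.485), SLC2A1 (0.62, adjusted p = 0.333), PYGL (0.11, adjusted p = 0.753), FABP7 (0.09, adjusted p = 0.931) and PLIN2 (0.01, adjusted p = 0.93) did not pass. Nor did NOTCH1 (-0.35, adjusted p = 0.0742), NOTCH2 (0.01, adjusted p = 0.978), JAG1 (-0.81, adjusted p = 0.105) and DLL4 (0.14, adjusted p = 0.671). PLIN2 lay near the array median here too, and DLL4 was flat across nearly all arrays, so little can be read from either result. NRARP, a Notch target with values of 2.95 to 3.41, was not tested because its probe set lay above the array median in too few arrays. FABP3 was not tested for the same reason, with its 2 probe sets at 4.64 and 4.20 in bevacizumab 1. In the other 8 arrays they lay at 2.61 to 3.09 and 2.56 to 2.76.

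Leaving out DBZ 1, 2 or 3 left 27, 45 or 46 genes changed with DBZ, leaving out bevacizumab 2 left 81, and leaving out control 2 left 99. Of the 149 genes, 24 (2 higher, 22 lower) passed with each array left out, among them HEY1, HEYL, NOTCH3, COL5A3, CCDC102B and AHNAK2. The other named calls were lost with at least 1 array left out. The highest adjusted p of all of them but HEY2, SERPINH1, ADAMTS1 and EBP is given here. Without DBZ 1 it was 0.0731 for AOX1, 0.0521 for NRIP3, 0.165 for HMGA1, 0.103 for MMP9, 0.118 for MMP13 and 0.156 for IBSP. The same array gave 0.0506 for POSTN, 0.0949 for COL5A1, 0.121 for COL5A2, 0.0647 for MMP11 and 0.159 for DCN. Without DBZ 2 it was 0.171 for STX1A, 0.0651 for CPA4, 0.173 for SERTAD2, 0.175 for HELLS, 0.0735 for HES1 and 0.05 for LUM. Over the 9 omissions STX1A and SERTAD2 kept their calls in 0, HELLS in 1, and HMGA1, IBSP and DCN in 2. The rest of the calls given here were kept in 3 to 8. Without control 3 the HIF list (adjusted p = 0.301), the cholesterol list (0.0965), the matrix protease list (0.0514) and the immediate early list (0.0551) lost their calls. The HIF list also lost its call without control 2 (adjusted p = 0.0532).

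The direct comparison of bevacizumab with DBZ asked where the 2 treatments differed. The Notch target HEY1 was higher with bevacizumab, at 7.51 ± 0.15, than with DBZ, at 6.45 ± 0.22 (log2 signal, mean ± SD, n = 3, adjusted p = 0.024). COL5A3 was 1.44 ± 0.18 (SE, log2) higher (adjusted p = 0.0369) and CCDC102B 1.19 ± 0.12 higher (adjusted p = 0.024). COL11A1 (-1.93 ± 0.20), the tight junction gene CLDN11 (-1.79 ± 0.15) and NDST4 (-1.50 ± 0.15) were lower with bevacizumab, each at an adjusted p of 0.024. The 3 probe sets of COL11A1 ranged from -1.93 to -0.13, with -1.12 by their mean. The flat values of COL11A1 and NDST4 with bevacizumab leave the size of these differences uncertain too. Also lower were the Wnt antagonist gene FRZB (-0.97 ± 0.11) and the Wnt receptor gene FZD7 (-0.91 ± 0.12). DKK2, another Wnt antagonist, was lower by its representative probe set (-0.88 ± 0.10), against 0.05 in the other. In all, limma called 20 genes, 6 higher and 14 lower with bevacizumab. The other named genes were LRRC17 (0.85 ± 0.11, against 0.44 in its other probe set), the polyamine enzyme gene SAT1 (0.48 ± 0.05), KITLG, stem cell factor (0.31 ± 0.04), the proteoglycan gene KERA (-1.39 ± 0.18, at a low 3.36 with bevacizumab) and CD248 (-0.82 ± 0.08).

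The gene calls between the treatments depended on which array was left out. With any DBZ or bevacizumab array left out the median change of the 14 lower genes stayed at -0.91 to -0.79 (-0.85 with all arrays). These genes were chosen for their differences in the same arrays, so the steady median is no independent support for their size. In all 20 genes the 2 groups did not overlap, so leaving out 1 array could not turn a sign. With DBZ 2, DBZ 3, bevacizumab 2 or bevacizumab 3 left out, limma called 0 genes (1258, 1125, 1239 and 1133 at an unadjusted p under 0.05). It called 1 gene without DBZ 1, 3 without bevacizumab 1, 12 without control 1 and 53 without control 3, and 0 with the spike-in covariate (1076 at an unadjusted p under 0.05).

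Cell cycle lists were lower with bevacizumab than with DBZ. Of 34 genes of G2 and mitosis none passed over all genes and 11 fell when adjusted over the list alone (median -0.15, adjusted p = 9.82e-11). The G2 list had adjusted p = 0.134 with an estimated correlation. It was led by the survivin gene BIRC5 (-0.37 ± 0.07, adjusted p = 0.0789), NEK2 (-0.33 ± 0.06, adjusted p = 0.0865) and UBE2C (-0.25 ± 0.05, adjusted p = 0.139). The mitotic kinase gene AURKB differed by -0.41 ± 0.08 (adjusted p = 0.0963), against 0.20 in its other probe set. Of 34 S phase genes none passed and 7 fell when adjusted over the list alone (median -0.15, adjusted p = 1.59e-09). The S phase list had adjusted p = 0.134 with an estimated correlation. MCM5 (-0.33 ± 0.06, adjusted p = 0.0798), UHRF1 (-0.26), RRM2 (-0.30) and DTL (-0.29) led it.

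Endoplasmic reticulum chaperones were higher with bevacizumab than with DBZ (median 0.12, adjusted p = 3.01e-07), with none of 22 passed and 2 risen when adjusted over the list alone. The chaperone list had adjusted p = 0.134 with an estimated correlation. DNAJB9 differed by 0.41, HSPA5 by 0.17, HERPUD1 by 0.32 (against -0.03 in its other probe set) and XBP1 by 0.34 (against -0.17 in its other probe set). Macrophage and granulocyte markers were higher (median 0.17, adjusted p = 0.0116), with none of 6 passed and 2 risen when adjusted over the list alone. The macrophage list had adjusted p = 0.134 with an estimated correlation. ADGRE1, the F4/80 antigen gene, differed by 1.08 ± 0.26 (adjusted p = 0.171), the lysosomal protease gene CTSS by 0.87 ± 0.13 (adjusted p = 0.0598), AIF1 by 0.31 and LYZ by 0.04. The p53 target list was higher as well (median 0.12, adjusted p = 0.00304), with none of 23 passed over all genes or over the list alone. The p53 list had adjusted p = 0.134 with an estimated correlation. ZMAT3 (0.19), TP53INP1 (0.40), TIGAR (0.18) and PHLDA3 (0.14) led it. The matrix protease list, which holds proteases and their inhibitors, was higher (median 0.08, adjusted p = 0.00877). Its 1 changed member of 24, ADAMTS1, was lower with bevacizumab. Adjusted over the list alone, 3 rose and 1 fell. The matrix protease list had adjusted p = 0.246 with an estimated correlation. MMP11 (0.72), the protease inhibitor gene TIMP3 (0.70), PLAU (0.28) and MMP9 (1.15) did not pass.

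A further 6 lists passed between the treatments but lost their calls with 1 array left out, and none of their members passed over all genes. The glycolysis list (20 genes) had a median of -0.11 (adjusted p = 0.00529), and adjusted p = 0.0649 without DBZ 1. The glycolysis list had adjusted p = 0.471 with an estimated correlation. HK1 (-0.17), SLC2A1 (-0.60), PFKM (-0.12) and GPI (-0.17) led it. The YAP and TEAD target list (20 genes) had a median of -0.16 (adjusted p = 0.0186), with 0.0649 without DBZ 1 and 0.211 without bevacizumab 1. The YAP list had adjusted p = 0.134 with an estimated correlation. RBMS3 (-0.52), FJX1 (-0.28), PTPN14 (-0.14) and ASAP1 (-0.20) led it. The receptor tyrosine kinase feedback list (22 genes) had a median of -0.12 (adjusted p = 0.0186), with 0.13 without DBZ 2 and 0.171 without bevacizumab 1. The kinase list had adjusted p = 0.349 with an estimated correlation. FOSL1 (-0.51), SPRY1 (-0.46), EGFR (-0.31) and DUSP5 (-0.20) led it.

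The fatty acid synthesis list (11 genes) had a median of 0.19 between the treatments (adjusted p = 0.0186), with 0.0867 without DBZ 2 and 0.218 without bevacizumab 2. The fatty acid list had adjusted p = 0.471 with an estimated correlation. SCD (0.78), SREBF1 (0.21), ELOVL5 (0.19) and THRSP (0.12) were its members with the smallest p. The autophagy and lysosome list (24 genes) had a median of 0.09 (adjusted p = 0.0176), with 0.0731 without bevacizumab 2 and 0.0548 without bevacizumab 3. The autophagy list had adjusted p = 0.134 with an estimated correlation. CTSL (0.33), BECN1 (0.19), HEXA (0.15) and CTSB (0.17) were its leading members. The ATF4 list (34 genes) had a median of 0.14 (adjusted p = 0.0459), with 0.0532 without control 2, 0.33 without DBZ 2 and 0.979 without bevacizumab 2. The ATF4 list had adjusted p = 0.814 with an estimated correlation. NARS1 (0.28), CHAC1 (0.50), SESN2 (0.36) and CTH (1.00) were its leading members. Adjusted over the list alone, 1 gene fell in the kinase list and 1 rose in the autophagy list, and none passed in the other 4.

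Both treatments were compared with the same 3 controls, which alone makes their changes alike. Of the changed genes 67 were lower in both comparisons, 8 were higher in both, and 0 went in opposite directions. Independent lists of these sizes would share 1.45 and 0.111, and in 100 simulations of unchanged groups against shared controls at most 0 genes were called in both. The first value leaves out the shared controls and the second the effects of the treatments. The controls were too few to split, so part of the excess of shared calls may come from the shared controls. The 67 included HEY1, HEYL, HEY2, NOTCH3, COL5A3, COL5A1, POSTN, BGN, DCN, LUM, FRZB, CD248, TAGLN and CCDC102B. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.63, against a mean of 0.50 (0.39 to 0.57) in those simulations. Of all genes 71.6% had the same sign, against 66.6% (65.1% to 67.4%). The covariance was 0.0305, against 0.00883 (0.00729 to 0.011). Shared controls add the same covariance with or without effects of the treatments. With equal spreads in all groups, the difference of 0.0217 would estimate what the treated groups share beyond that. The simulation drew each gene independently and with the same spread in all groups. The controls lay farther from the others of their group (root mean square distance 0.18 to 0.288) than the DBZ arrays did (0.144 to 0.163). For bevacizumab the distance was 0.169 to 0.228. A wider spread of the shared controls alone raises r, the shared signs and the covariance. The excess of r and of shared signs therefore cannot by itself show shared effects, and 0.0217 may be too large. Any difference in the handling of control and treated arrays would enter this estimate as well.

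**Figure D3:**
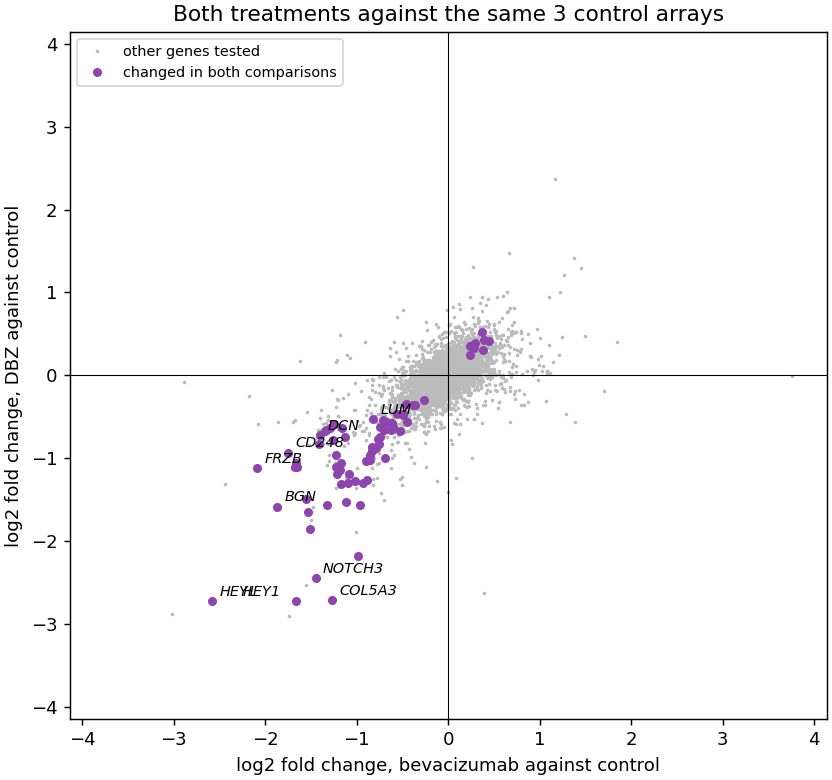
Log2 fold change of each gene tested with bevacizumab (horizontal) and with DBZ (vertical) against the same 3 control arrays, with the genes changed in both comparisons in purple and some of them named. Of these, 67 lie at lower left and 8 at upper right, and HEYL lies at -2.58 and -2.72.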

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

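The tests of single control arrays, of the spike-in trend, of separate handling, of host markers and of the cell cycle lists were chosen after the results they weigh were seen; the counts over other splits of the arrays were planned before. Probe sets for 18S ribosomal RNA, which enter no comparison, had a mean log2 signal of 10.67 in DBZ 2 and 11.03 in bevacizumab 3, above the 9.2 to 9.64 of the controls, and this signal outside the main measurement drew attention to those arrays. In the other 4 treated arrays the mean was 8.72 to 8.78, below each control. The probe set for the 5' part of 28S ribosomal RNA was higher in all 3 bevacizumab arrays (10.61, 10.83 and 11.42) than in the controls (10.32 to 10.41), and at 10.39 to 10.62 with DBZ. No biological explanation of these values was tested.

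Notch target, collagen and fibroblast and pericyte genes lay lower as a group under both treatments (50 genes together, median -0.44 with bevacizumab and -0.38 with DBZ). With an estimated correlation only the Notch target list with DBZ passed (adjusted p = 0.0347); the Notch target, collagen and pericyte lists with bevacizumab (0.0523, 0.18 and 0.0614) and the collagen and pericyte lists with DBZ (0.196 and 0.0582) did not. The tables argue against a single control array as the source: with each control left out in turn the median stayed at -0.31 or below, and its bootstrap interval over genes below 0 in both comparisons. They argue against the trend that the bacterial spike-ins follow within groups as the whole cause, since with it as a covariate, which moved the genes by a median of 0.149 and 0.097, the weaker of the 2 medians was -0.35 (interval -0.53 to -0.31). The bootstrap intervals measure the spread between genes, which are not independent replicates, and not between tumours. The result with the covariate holds for the group and not for each gene. With bevacizumab HEY1 went from -1.66 ± 0.12 to -1.34 ± 0.27 and BGN from -1.87 ± 0.09 to -1.59 ± 0.21, with larger standard errors, while NOTCH3 went from -1.45 ± 0.25 to -0.60 ± 0.53, so that most of its change was lost as well. Controls handled apart from treated arrays cannot be told apart from treatment, because the lowest control exceeded the highest treated array by 0.04 in the hybridization spike-ins and no label names a batch. Less host RNA of every cell type stays open too. With bevacizumab 8 endothelial and macrophage markers with control means of at least 5 lay 0.67 above 15 fibroblast and pericyte markers. With DBZ they lay 0.35 above them. The exact two-sided permutation p was 0.0115 with bevacizumab and 0.136 with DBZ. These permutations exchanged marker genes and not arrays, so the p-values treat genes as independent replicates, which they are not. The difference with bevacizumab leaned on the macrophage markers ADGRE1 (1.11) and CTSS (0.55), while the rest of the 8 changed by -0.27 to 0.24. A loss of fibroblasts and pericytes, lower Notch activity in them and lower expression in tumour cells therefore remain hypotheses.

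Genes of S phase and mitosis were higher with DBZ than with control and with bevacizumab (68 genes together, median 0.15 in both comparisons). The weakest median was 0.11 with any array of the 2 groups compared left out. Leaving out an array of the remaining group cannot move it. With the spike-in mean as a covariate the weaker median was 0.15. Each bootstrap interval over genes lay above 0, which argues against a single array and against the spike-in trend as the whole cause. These intervals too measure the spread between genes and not between tumours. A candidate explanation is a larger share of cycling tumour cells after DBZ; it was not tested, the differences are small, and neither list passed with an estimated correlation.

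With 3 arrays against 3 there are 10 splits, so the share of splits with as many changed genes is never under 0.1, too large to exclude chance. Only the real split of each comparison (1 of 10) gave as many: 192 genes with bevacizumab against control, with 1 as the highest of the other splits, 149 with DBZ against control, with 0, and 20 with bevacizumab against DBZ, with 0.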

How the results depend on the processing

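Leaving out 2 arrays together and the spike-in covariate were chosen after seeing the data; the other settings were planned. The lower collagen (medians -0.44 to -0.29 with bevacizumab, -0.33 to -0.20 with DBZ) and fibroblast and pericyte lists (-0.61 to -0.42 and -0.50 to -0.38) passed in 24 of 25 settings each, and the Notch target list in 23 of 24 with bevacizumab (medians -0.67 to -0.08) and 24 of 24 with DBZ (-0.63 to -0.09); the exception was the estimated correlation. The Notch medians nearest 0 came without the filter on low values, against -0.57 and -0.56 with it, so their size depends on that filter. No call of a named gene reversed in any setting, while in 509 of their fits a call was lost and in 61 one was gained. Among all called genes, signs turned with only probe sets free of shared-sequence suffixes. They did so for 4 of the 152 genes still present with bevacizumab against control and 1 of 111 with DBZ against control. Reversals of lists were counted only where the list passed in the main fit or in the setting. Among these the direction of the test reversed for 2 lists, both with bevacizumab against control and the spike-in covariate: fatty acid synthesis (its median stayed above 0 at 0.04, adjusted p = 0.659) and interferon response (median 0.23, adjusted p = 0.0473). Medians of 4 lists that had passed crossed 0 in 1 setting each, with the call lost: ATF4 between the treatments (-0.01 without bevacizumab 2), autophagy between the treatments (-0.02 with only probe sets free of shared-sequence suffixes), and, with the spike-in covariate, TGF-beta targets with bevacizumab (0.01) and oxidative phosphorylation with DBZ (0.01). The cause was not tested.

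Counts of changed genes depended strongly on the setting. For bevacizumab against control (192) they were 127 at a fold of at least 1.5, 111 without the filter, 28 with only the 6 arrays compared (0 higher and 28 lower, against 34 and 158), 82 without control 3 and bevacizumab 3, 30 without DBZ 2 and bevacizumab 3, 3 with the spike-in covariate, and 59 to 159 with each array left out. Centring each array on its median called 53 higher and 136 lower (72% lower against 82.3%). For DBZ against control (149) they were 84 at that fold, 94 without the filter, 98 with only probe sets free of shared-sequence suffixes, 39 with 6 arrays (6 higher and 33 lower, against 39 and 110), 286 with array weights, 27 without DBZ 2 and bevacizumab 3, 7 with the spike-in covariate, and 27 to 152 with each array left out. For bevacizumab against DBZ (20) they were 12 without the filter, 42 with the stricter filter, 13 with the mean of all probe sets, 6 with 6 arrays (1 higher and 5 lower, against 6 and 14), 39 with trend and robust settings, 346 with array weights, 3 and 1 without those 2 pairs of arrays, 0 with the spike-in covariate (1076 genes at an unadjusted p under 0.05), and 0 to 53 with each array left out. Fewer arrays leave fewer residual degrees of freedom; for the other settings the cause was not tested.

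Counts of lists past the test were 8, 12 and 12 for bevacizumab against control, DBZ against control and bevacizumab against DBZ. They were 0, 1 and 0 with an estimated correlation, 5, 7 and 6 with fry, and 6 to 15, 9 to 16 and 9 to 14 with each array left out; array weights gave 15 for the first, and probe sets free of shared-sequence suffixes 7 for the last. The correlation of the treatments' effects (0.63) was 0.57 to 0.70 with each array left out.

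The replicate numbers did not pair the arrays: residuals of arrays with the same number correlated at 0.15, 0.06 and 0.25 for bevacizumab and control, 0.08, -0.27 and -0.16 for DBZ and control, and -0.22, -0.22 and -0.26 for bevacizumab and DBZ, and not every array correlated best with its own number. With the replicate block, 71, 57 and 4 genes were called. Signals near the array median, such as HEYL in treated tumours, limit how far a fall can be measured.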

Other observations

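Gene groups that passed in no comparison are given here with their median log2 change and camera adjusted p, first for bevacizumab and then for DBZ against control. Notch receptors and ligands had -0.02 (0.744) and -0.03 (0.342), gamma-secretase subunits 0.11 (0.319) and -0.07 (0.884), glycogen metabolism -0.04 (0.921) and 0.07 (0.338), and fatty acid uptake and lipid droplets 0.01 (0.441) and 0.06 (0.225). Heat shock proteins had -0.09 (0.0567) and -0.08 (0.072), NRF2 targets 0.08 (0.527) and 0.08 (0.338), metallothioneins -0.02 (0.826) and 0.06 (0.461), cytosolic ribosomal proteins 0.02 (0.0981) and 0.01 (0.541), and ribosome biogenesis -0.01 (0.892) and 0.01 (0.387). Inflammatory NF-kB targets had 0.24 (0.175) and 0.08 (0.894), interferon response genes -0.15 (0.265) and -0.05 (0.072), angiogenic ligands and receptors 0.00 (0.892) and 0.05 (0.27), neural stem and glioma markers 0.08 (0.216) and 0.08 (0.072), and mesenchymal transition regulators -0.05 (0.216) and -0.07 (0.0778).

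Markers of other host cells gave -0.06 (0.826) and 0.01 (0.884) for endothelium, -0.27 (0.265) and -0.23 (0.338) for skeletal muscle and 0.07 (0.744) and 0.27 (0.432) for skin epithelium. For endothelium with DBZ the mean, -0.12, and the test lay on the other side of 0 from the median. The endothelial list held EMCN, at 4.41 in controls, 3.27 with bevacizumab and 3.56 with DBZ (adjusted p = 0.232 and 0.444), and PECAM1, at a control mean of 6.51 and changes of -0.20 and -0.17; EMCN, PECAM1 and, in these comparisons, ADGRE1 were chosen after their values were seen. ADGRE1, a macrophage marker, differed by 1.11 ± 0.26 (SE, log2) with bevacizumab (adjusted p = 0.0902) and by 0.03 with DBZ (adjusted p = 0.975).

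Control 3 stood apart from the other controls. Its root mean square distance to its own group was 0.288, the largest of the 9 arrays, and on the first 2 principal components it lay at -22.5 and -15.2, against -7.48 and 14.4 for control 1 and -8.88 and 6.81 for control 2. Without it 6 of the list calls against control were lost, 2 with bevacizumab and 4 with DBZ. It was kept in the main fit, since 3 arrays are too few to call 1 of them wrong.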
